A study of Homo sapiens with 2 samples.

How the data were processed

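RNA was extracted from cultured MHCC97H and MHCC97L cells with Trizol, and libraries were made with a poly(A) isolation module and an NEBNext Ultra RNA kit, per the labels' protocols. The deposited table gives raw read counts per gene for the 2 libraries, with no normalisation. The columns were assigned to the lines through the labels' descriptions. Per the submitters' processing notes, bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.2 and the build hg19 were used. The annotation, strand setting and treatment of multi-mapping reads are not given in the sources used here. Counts that ignore strand or split reads between paralogs would make overlapping genes and near-identical families uncertain.

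The counts were taken as deposited. Effective library sizes were computed by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.06 for MHCC97H and 0.942 for MHCC97L. CPM values use these effective sizes, except the floors, which use total counts. Genes with at least 1 CPM in at least 1 library were kept, 14578 in all, of which 12371 are protein coding. Log2 ratios of MHCC97H over MHCC97L used a prior count of 0.5. The 95% interval of a ratio is the exact Clopper-Pearson interval of the binomial split of the gene's reads. A gene met the size rule with an absolute log2 ratio of at least 1 and an interval that excluded equal expression. With 1 library per line no test across samples exists and no p-value is given. Named genes were the 10 with the largest interval bound nearest equality in each direction, among genes with symbols of at least 10 CPM in the higher library, up to 6 RBP genes per direction by the same bound with no CPM minimum beyond the filter, and 2 to 4 members of each list of at least 5 CPM that met the rule with the largest ratios, or the 2 most abundant where fewer than 2 met it. Where 5 or fewer members of a list met the rule, those outside these choices were also named, after their values were seen. A few genes that these rules select are not reported here. The named-gene rules, the size rule, the comparison with random lists and 43 gene lists were fixed before the data were examined, and the main values are those.

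For each list the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart outside the central 95% of these, as a description of these libraries. The RBP union named 501 genes, of which 497 were in the table and 461 were kept. Gene names, neighbours and transcript properties came from GENCODE release 29 and RefSeq, whose build differs from that of the counts, so no coordinates are given. After the data were seen, a lowess trend of the log2 ratio with transcript GC content, alone or with log2 length, was removed with a span of 0.2, for the 13891 kept genes with a value (95.3%). The standard deviation of the log2 ratio was 0.68 before and 0.54 after removal of both.

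Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used, and DESeq2 1.42.0 gave median-of-ratios factors. Alternatives covered scaling, filter, fold threshold, interval, prior count, an assumed coefficient of variation and the trend. The steps were tested on simulated data made from the libraries' means. With counting error only, over 14312 genes, 21 of 14112 unchanged genes met the rule, as did all genes changed 2.5-, 4- or 8-fold and none changed 1.5-fold. With the trend with GC content and length planted and left in, 169 of 14131 otherwise unchanged genes met the rule. So did 26.5% of genes changed 1.5-fold and 67.3% of those changed 2.5-fold, and 33.8% of intervals covered the planted ratio. The otherwise unchanged genes had no spread beyond counting error, unlike the data, so 169 can understate the calls that depend on the trend. In the data, 271 of the 1029 higher and 343 of the 678 lower genes also met the rule with the trend removed. With an assumed coefficient of variation of 0.2 per library, 405 of 14126 unchanged genes met the rule, and with 0.4, 3529 of 14230. Planned chromosome medians were not run, and runs of neighbouring genes in RefSeq order were tested instead. A planned comparison with the authors' own calls was not run, since the table holds counts without calls.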

Results

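The series profiled poly(A)-selected RNA from MHCC97H and MHCC97L, established human hepatocellular carcinoma cell lines described by the submitters as having high and low spontaneous metastatic potential. Its title gives the aim as a screen for RNA-binding protein (RBP) genes related to metastasis. Each line was represented by 1 library, with 28967153 counted reads for MHCC97H and 24964246 for MHCC97L. Of 44591 genes in the table, 22476 had at least 1 read in the MHCC97H library and 22004 in the MHCC97L library. Protein-coding genes took 96.7% of the reads in each library, and mitochondrially encoded genes took 2.71% in MHCC97H and 2.78% in MHCC97L. Reads of cytosolic ribosomal protein genes made up 8.57% of the MHCC97H library (95% exact interval 8.56 to 8.58) and 12.3% of the MHCC97L library (95% exact interval 12.25 to 12.28). A count of 0 allowed up to 0.104 CPM (counts scaled to the library total) in MHCC97H and 0.120 CPM in MHCC97L. Without replicates no difference below has a replicate check, and every comparison is between these 2 libraries, not between the lines as conditions. Intervals and floors cover counting error only, since each line has 1 library. PCR reads without molecular identifiers are not independent molecules, so even that error may be understated.

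The comparison of MHCC97H with MHCC97L asked which genes differ between a more and a less metastatic line. The top gene higher in the MHCC97H library was MEX3C, an RNA-binding ubiquitin ligase, at 41.0 CPM against 6.72 CPM, a 6.09-fold difference (95% counting interval 5.17 to 7.25). TMX3, a thioredoxin-related protein of the endoplasmic reticulum, was 5.18-fold higher (3.97 to 6.96). The mitotic genes HMMR and CENPF were 4.82-fold (3.65 to 6.55) and 3.65-fold (3.20 to 4.18) higher. The metalloprotease gene ADAM9 was 4.03-fold higher (3.48 to 4.71), and the EGF receptor ligand EREG was 3.55-fold higher (3.28 to 3.86). The genes lower in the MHCC97H library were led by the betaine transporter gene SLC6A12, at 3.84 CPM against 42.5 CPM, a log2 ratio of -3.46 (95% counting interval -3.76 to -3.19).

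Other leading genes on the higher side were LRRC58 (log2 ratio 2.21), the succinate receptor gene SUCNR1 (1.94), and the Wnt antagonist gene DKK1 (1.81). The Wnt receptor gene FZD6 was 3.90-fold higher (3.12 to 4.95). On the lower side, the haem oxygenase gene HMOX1 had a log2 ratio of -2.52 (95% counting interval -2.66 to -2.39). The steroid-metabolising reductase gene AKR1C1 stood at -2.43, although reads of its near-identical paralogs make that value uncertain. NOTUM, which encodes a secreted Wnt inhibitor, stood at -2.28, PAQR8 at -2.16, DSCAML1 at -2.17 and the calcium-binding protein gene S100A4 at -2.02. MRPS6 stood at -2.47, but it overlaps SLC5A3. The overlapping genes FXYD2 and FXYD6-FXYD2 stood at -2.25 and -2.21, and reads of either could count for the other. HMMR, SUCNR1, ADAM9, EREG, CENPF, FZD6, SLC6A12, AKR1C1, DSCAML1 and S100A4 also overlap other annotated genes, and no strand setting is given, so their reads are not certain to be their own. The same limit holds for many of the genes named below.

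By the size rule, an absolute log2 ratio of at least 1 with a counting interval that excludes equal expression, 1029 of 14578 kept genes were higher in the MHCC97H library (7.06%) and 678 were lower (4.65%). The remaining 88.3% did not meet the rule. The share of kept genes within 2-fold was also 88.3%. The interval condition therefore removed no gene, and the rule acted here as a plain 2-fold cutoff. The Spearman correlation of log2 CPM between the libraries was 0.970 across genes, which are not independent replicates. Of all genes meeting the rule, 60.3% were higher in MHCC97H, a share that became 77.9% when total counts replaced the trimmed mean of M-values (TMM) scaling, since total counts moved every log2 ratio by 0.17. The ratio also depended on the base composition of the transcript. Its Spearman correlation across genes was -0.64 with GC content and 0.36 with length. In the lowest of 10 equal groups of genes by GC content (27.8 to 39.2%) the median log2 ratio was 0.73, with 393 genes higher and 8 lower. In the highest (62.7 to 76.7%) it was -0.45, with 10 higher and 142 lower. With the trend with GC content and length removed, a step chosen after the data were seen, 363 genes were higher and 483 lower, of which 271 and 343 also met the rule before removal. After this step the higher share was 42.9%, and all 10 leading genes on each side still met the rule. The log2 ratios of the leading higher genes were smaller, at 2.07 for MEX3C, 1.60 for TMX3, 1.56 for HMMR, 1.53 for DKK1, 1.46 for LRRC58, 1.37 for ADAM9, 1.29 for FZD6, 1.22 for CENPF, 1.13 for SUCNR1 and 1.06 for EREG. Those of the leading lower genes moved both ways. AKR1C1 (-2.97) and PAQR8 (-2.50) were lower still. SLC6A12 (-3.31), MRPS6 (-2.32), HMOX1 (-2.19), DSCAML1 (-1.98), NOTUM (-1.81), FXYD2 (-1.63), FXYD6-FXYD2 (-1.62) and S100A4 (-1.59) were nearer equality.

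**Figure D1:**
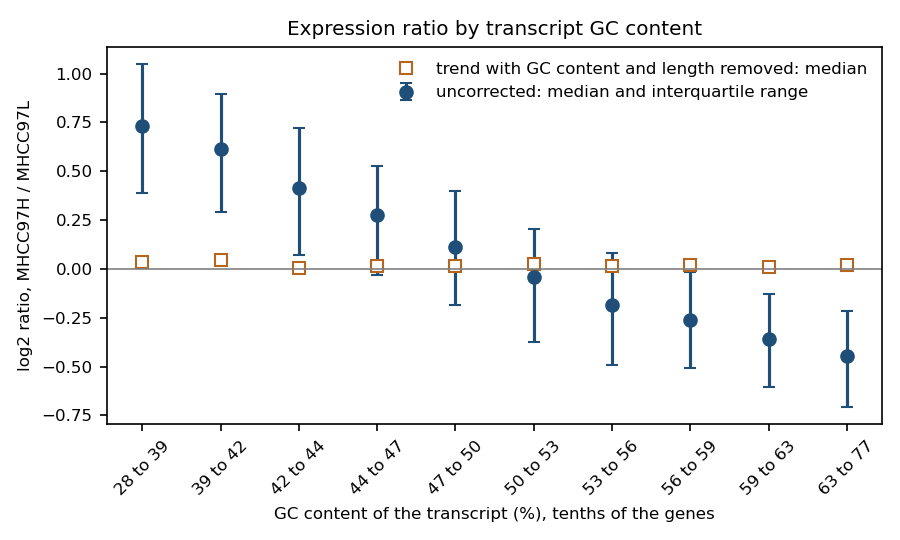
Log2 ratio of MHCC97H over MHCC97L (vertical axis) for kept genes in 10 groups of equal size by transcript GC content in percent (horizontal axis). Filled circles are medians with the interquartile range as bars, and open squares are medians with the trend with GC content and length removed. Uncorrected medians run from 0.73 in the lowest group to -0.45 in the highest.

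Among the RBP genes, the subject of the series, 30 of 461 kept genes were higher in the MHCC97H library and 3 were lower. Over all kept genes the shares were 7.06% higher and 4.65% lower. At this 2-fold cutoff RBP genes were not over-represented among the higher genes, and few were among the lower genes. At a 1.5-fold threshold, 108 RBP genes were higher and 69 lower, against 2813 and 2009 of all kept genes. Those were larger RBP shares on both sides. The leading genes on the higher side after MEX3C were the nucleolar helicase gene DDX21, at 115.5 CPM against 36.9 CPM (3.13-fold, 2.91 to 3.38), YTHDC2, which encodes an m6A reader (2.96-fold, 2.40 to 3.70), and the mRNA decapping enzyme gene DCP2 (2.93-fold, 2.45 to 3.52). TIA1, a stress granule component, was 2.66-fold higher (2.23 to 3.19), and SYNCRIP, an hnRNP family member, was 2.44-fold higher (2.30 to 2.60). The 3 lower genes were CELF5, with 2 reads against 25 (log2 ratio -3.70, interval -7.15 to -2.03), KHDRBS3, with 18 reads against 49 (-1.80, interval -2.70 to -1.03), and the ribosomal protein gene RPS29 (-1.05). The RBP genes had a median log2 ratio of 0.16, and those outside the ribosome had a median of 0.27 over 384 genes, which became 0.056 and 0.15 with the trend removed. With the trend with GC content and length removed, the RBP counts became 6 higher and 10 lower of 460 genes with a value. Over all 13891 genes with a value they were 363 and 483, so neither RBP share was above that of all genes. MEX3C, DDX21, CPEB3, ZC3H12C and NANOS1 were higher under both treatments, and CELF5 and KHDRBS3 lower, CPEB3 and NANOS1 being named after their values were seen. YTHDC2, DCP2, TIA1 and SYNCRIP no longer met the rule, with corrected log2 ratios of 0.91, 0.77, 0.66 and 0.99.

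**Figure D2:**
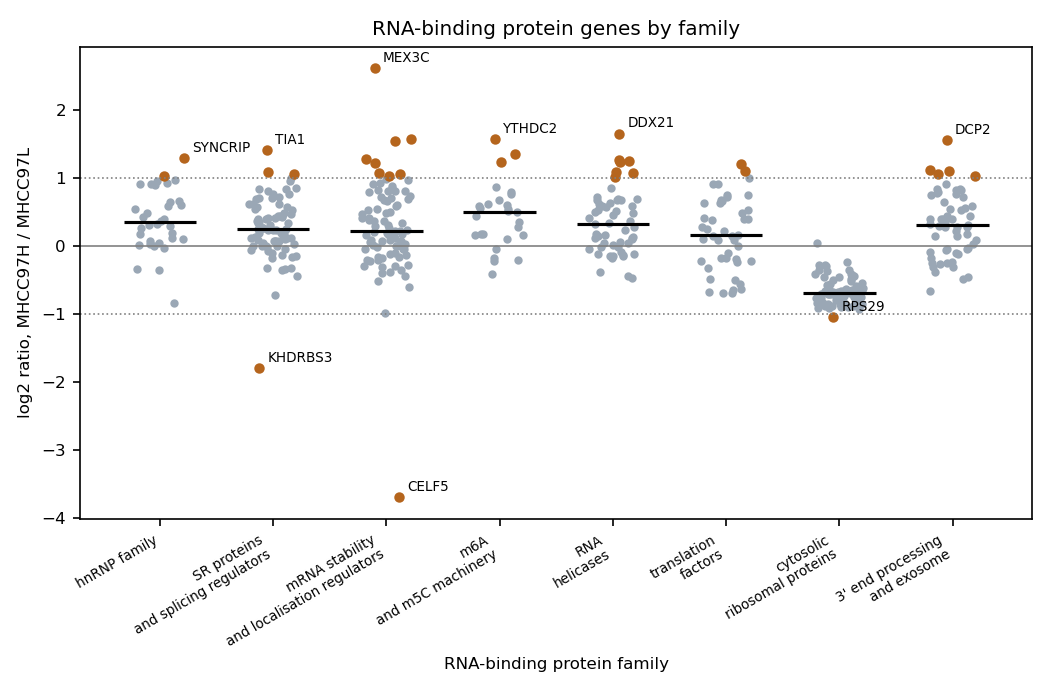
Log2 ratio of MHCC97H over MHCC97L (vertical axis) of each kept RBP gene, by family (horizontal axis). Each point is a gene, coloured where it met the size rule, black lines are family medians and dotted lines mark log2 ratios of 1 and -1. Cytosolic ribosomal protein genes lie at a median of -0.70, while every other family has a median above 0.

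Most RBP families leaned the same way. The m6A and m5C machinery had the highest family median, 0.49 over 27 genes, with 3 higher (YTHDC2, the pseudouridine synthase gene PUS7 at 1.34 and the m6A methyltransferase subunit gene METTL14 at 1.23). The hnRNP family had a median of 0.34 over 34 genes, and the 2 that met the rule were SYNCRIP and HNRNPA2B1 (1.02). RNA helicases had a median of 0.33 over 55 genes with 7 higher, among them DDX18 (1.27), DHX29 (1.25) and DDX46 (1.24). SR proteins and splicing regulators had a median of 0.24 over 81 genes, with TIA1, SRPK1 (1.09) and RBM47 (1.05) higher and KHDRBS3 lower. Regulators of mRNA stability and localisation had a median of 0.22 over 87 genes with 8 higher, including ZC3H12C (1.54), CAPRIN2 (1.27) and LARP4 (1.22), and CELF5 lower. The medians of these 5 families lay above the central 95% of random lists matched on expression, both before and after the trend was removed. After removal the medians were smaller, at 0.24, 0.18, 0.16, 0.17 and 0.11 in the order given, and the numbers of higher genes were 1, 0, 1, 0 and 4. The 1 in the m6A and m5C machinery list was WDR4 (1.11), which had not met the rule before. That list also holds genes of other RNA modifications, WDR4 and PUS7 among them. The helicase gene DDX60L (-1.10) was newly lower. PUS7 (0.84), METTL14 (0.50), HNRNPA2B1 (0.72), DDX18 (0.64), DHX29 (0.64), DDX46 (0.71), SRPK1 (0.60), RBM47 (0.73), CAPRIN2 (0.92) and LARP4 (0.41) no longer met the rule. Genes of 3' end processing and the exosome had a median of 0.30 over 57 genes, with DCP2, CNOT6L, XRN1, EXOSC9 and CNOT6 higher. DCP2 overlaps MCC, and EXOSC9 overlaps the mitosis gene CCNA2, so their reads are not certain to be their own. Translation factors had a median of 0.15 over 44 genes, with EIF1AX and EIF4E higher. Both lists stood above random lists only before removal, with percentiles of 69.8 and 76.8 after it. With the trend removed neither list had a higher gene, and the translation factor gene EIF3F (-1.22) was lower. Cytosolic ribosomal protein genes went the other way. Of 77 genes, 76 had a negative log2 ratio, and the median was -0.70 (95% interval of the median -0.73 to -0.65), or -0.48 with the trend removed. The abundant RPS2 stood at 4013 CPM against 7440 CPM, and RPLP0 at 3586 CPM against 6097 CPM. Before the trend was removed RPS29 alone met the size rule. After it RPS29 stood at -0.67 and did not, while 6 others did, with RPL37 (-1.42) and RPL37A (-1.20) the lowest.

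Cell cycle genes were higher in the MHCC97H library. Of 58 mitosis and G2/M genes, 26 were higher and none was lower, with a median log2 ratio of 0.95 against a central 95% of random lists of -0.16 to 0.20. Examples were HMMR (2.27), the spindle protein gene DLGAP5 (2.15), CENPF (1.87) and the kinetochore gene CENPK (1.68). Of 50 DNA replication and G1/S genes, 15 were higher and none was lower, with a median of 0.69. Among them were the nuclease gene EXO1 (1.99), MCM10 (1.60), the ribonucleotide reductase subunit gene RRM1 (1.56) and BRCA1 (1.43). With the trend removed these medians were 0.63 and 0.65, still above the central 95% of random lists, with 8 and 6 genes higher, and CENPK (0.96) and BRCA1 (0.86) no longer met the rule. Replication-dependent histone genes ran in the opposite direction, with 1 higher (HIST2H4B, 2.20, interval 0.92 to 4.01) and 6 lower of 21 and a median of -0.55. HIST1H2AE (-1.22) and HIST1H1C (-1.08) were examples. With the trend removed the median was -0.35, HIST1H4H (-1.34) alone was lower, and HIST1H2AE (-0.67) and HIST1H1C (-0.53) no longer met the rule. Poly(A) selection captures few histone transcripts, which mostly lack poly(A) tails.

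**Figure D3:**
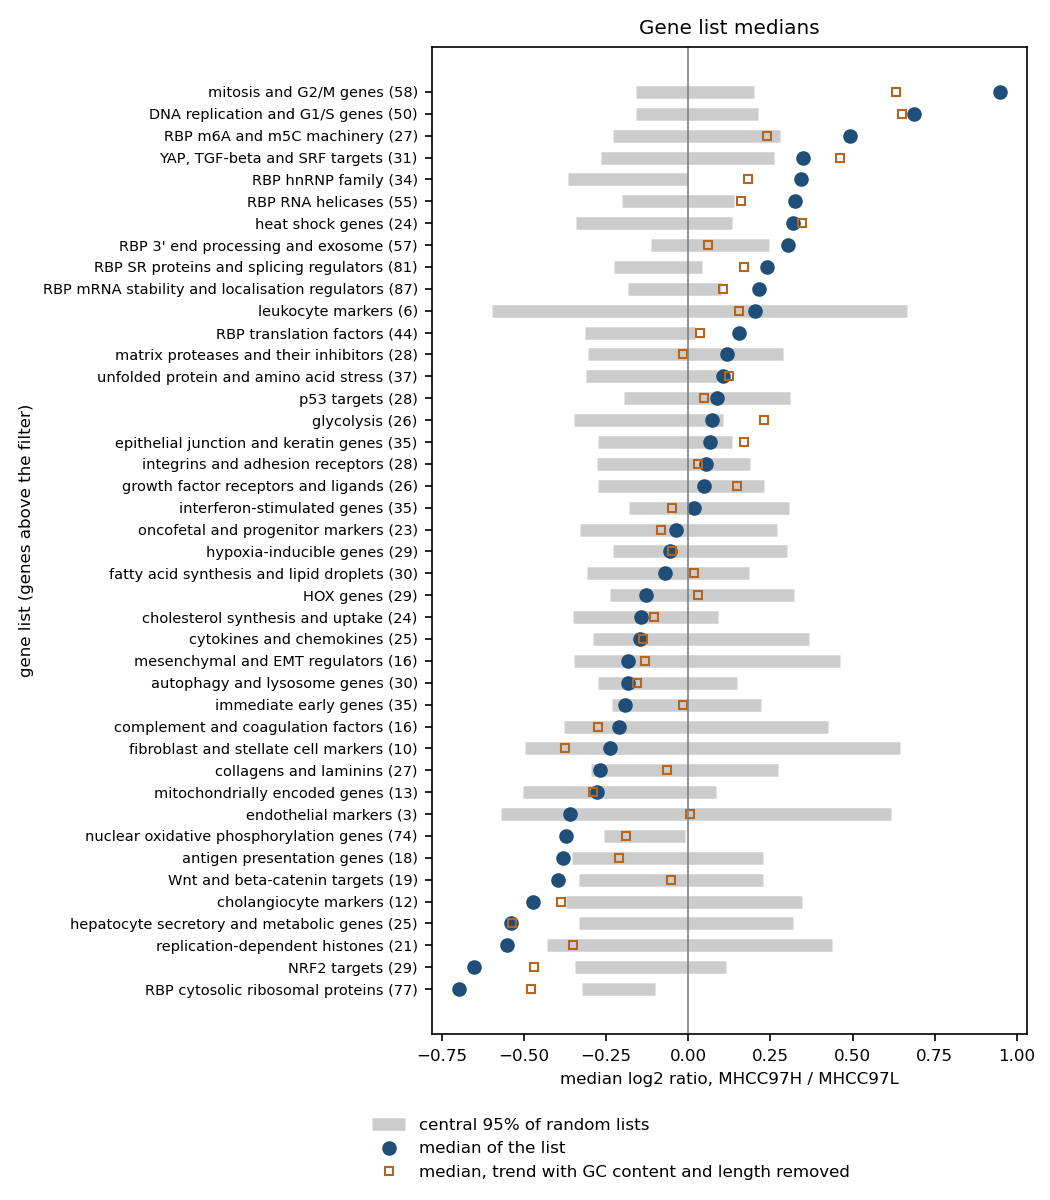
Median log2 ratio of MHCC97H over MHCC97L (horizontal axis) of each gene list with kept members (vertical axis, number of genes in brackets). Filled circles are uncorrected medians, grey bars the central 95% of random lists matched on expression for these, and open squares medians with the trend with GC content and length removed. Mitosis genes lie highest at 0.95 and cytosolic ribosomal protein genes lowest at -0.70.

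Gene lists tied to invasion did not stand apart from random lists. Of 16 mesenchymal and EMT regulators, FAP (1.11) and CYR61 (1.05) were higher and S100A4 was among the lower genes, with a median of -0.18 at percentile 11.9. Of 35 epithelial junction and keratin genes, OCLN (1.09) was higher and MUC1 (-1.41) and KRT7 (-1.20) lower, with a median of 0.07, which stood above random lists (percentile 99.1, median 0.17) only with the trend removed. Of 28 matrix proteases and inhibitors, ADAM9 and CTSK (1.08, interval 0.08 to 2.25) were higher. The abundant CTSD and TIMP1 had log2 ratios of -0.86 and -0.57. Of 27 collagens and laminins, COL4A5 (-1.34), COL1A2 (-1.25) and COL6A3 (-1.09) were lower, at median -0.27, and HSPG2 and LAMA5 had log2 ratios of 0.33 and -0.27. Of 28 integrins and adhesion receptors, ITGB6 (1.20) was higher, while CD44 and CD151 had log2 ratios of 0.22 and -0.36, within a list median of 0.05. With the trend removed, FAP (0.50), OCLN (0.42), KRT7 (-0.73), CTSK (0.95) and ITGB6 (0.57) no longer met the rule.

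Hepatocyte genes were lower in the MHCC97H library. Of 25 hepatocyte secretory and metabolic genes, 7 were lower and none was higher, with a median of -0.54 before and after the trend was removed. AMBP stood at 4.16 CPM against 14.0 CPM and albumin (ALB) at 1.85 CPM against 5.57 CPM. Of 16 complement and coagulation genes, PROC (-1.66), C3 (-1.60), C2 (-1.42), CFD (-1.32) and F10 (-1.26) were lower. The median of that list was -0.21 and stood below random lists only with the trend removed (-0.28, percentile 2.45), when CFD (-0.72) and F10 (-0.86) no longer met the rule. With a filter at 5 CPM its median was 0.14. Of 12 cholangiocyte markers, AQP1 (-1.51), MUC1, KRT7 and TFF3 (-1.10) were lower and CFTR (1.19) and ONECUT2 (1.01) higher, with a median of -0.47, or -0.39 with the trend removed, when AQP1, MUC1 and SPP1 (-1.02) were lower and none was higher. The 23 oncofetal and progenitor markers had a median of -0.04, with ALDH1A3 (1.55) and TERT (1.56) higher and ANPEP (-1.81) lower. Markers of other cell types did not stand apart. Fibroblast and stellate cell markers (10 kept) had a median of -0.24, with FAP higher and FBLN1 (-1.42), COL1A2 and PDGFRB (-1.12) lower, of which FAP and PDGFRB (-0.98) no longer met the rule with the trend removed. Endothelial markers (3 kept) had a median of -0.36, which was 0.45 with no filter and 0.004 with the trend removed, with EGFL7 (-1.12, or -0.60 with the trend removed) lower and ENG and ESAM at -0.36 and 0.26. Leukocyte markers (6 kept) had a median of 0.20, or -0.26 with no filter, with LYZ at 2693 CPM against 2443 CPM and LAPTM5 at 5.46 CPM against 10.5 CPM.

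Targets of NRF2, the transcription factor of the antioxidant response, were lower as a group. Of 29 genes, 7 were lower and ABCC4 (1.25) was higher, with a median of -0.65, or -0.47 with the trend removed. Besides HMOX1 and AKR1C1, examples were AKR1C2 (-1.93), which may share reads with its paralogs, and the epoxide hydrolase gene EPHX1 (-1.29). ABCC4 (0.73) and EPHX1 (-0.99) no longer met the rule with the trend removed. Heat shock genes had a median of 0.32 over 24 genes, above random lists (percentile 99.9), although 7 had a negative log2 ratio and the 95% interval of the median (-0.05 to 0.62) included 0. Those that met the rule were CHORDC1 (1.71), HSP90AA1 (1.14), HSPD1 (1.11) and HSPA6 (1.04), of which CHORDC1 and HSPA6 still did with the trend removed (list median 0.35). Genes of the unfolded protein and amino acid stress responses had a median of 0.11 over 37 genes, with HSP90B1 (1.22, or 0.78 with the trend removed) higher, and stood above random lists only before the trend was removed (percentile 96.9 after it), while CALR and ATF4 had log2 ratios of 0.11 and -0.45. Nuclear oxidative phosphorylation genes had a median of -0.37 over 74 genes, below random lists, although no member met the rule. With the trend removed, for the 60 genes with a value, the median was -0.19 and NDUFA4 (-1.39), COX7C (-1.23) and COX7B (-1.21) met it. The genes without a value include ATP5B, so the medians before and after removal cover different genes. The abundant ATP5B and SDHA had log2 ratios of -0.10 and 0.10. The 13 mitochondrially encoded genes had a median of -0.28, including COX1 (-0.32) and COX2 (-0.27), and stood below random lists only with the trend removed (-0.29, percentile 1.24).

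Genes of growth factor and developmental signalling gave mixed results. Targets of YAP, TGF-beta and SRF had a median of 0.35 over 31 genes, above random lists (percentile 99.5). TGFBR1 (1.57), TGFB2 (1.32), LATS2 (1.13), CNN1 (1.10, interval 0.18 to 2.16) and CYR61 were higher. With the trend removed the median was 0.46, still above random lists (percentile 100), with 4 genes higher and none lower. TGFBR1 (0.86) and TGFB2 (0.62) no longer met the rule. Wnt and beta-catenin targets had a median of -0.40 over 19 genes, with NOTUM and NKD1 (-1.35) lower and DKK1 higher, but with the trend removed the list no longer stood apart (-0.05, percentile 25.1). Immediate early genes (median -0.19 over 35) included the EGF receptor ligands AREG (1.71) and EREG, which were higher, and EGR2 (-1.52), which was lower. Of 26 growth factor receptors and ligands, ROR1 (1.48), SEMA3C (1.36) and EPHA4 (1.27) were higher and PDGFRB lower, with a median of 0.05. ROR1 still met the rule with the trend removed, and SEMA3C (0.69), EPHA4 (0.87) and PDGFRB did not. Of 28 p53 targets, SESN1 (1.23) and MDM2 (1.16) were higher, with a median of 0.09, and neither met the rule with the trend removed (0.82 and 0.71). HOX genes had a median of -0.13 over 29 genes, with HOXD1 (-1.48) lower and HOXB9 and HOXB6 at -0.31 and -0.25.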

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

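None of 124 named genes that met the rule reversed direction under any alternative run here. These genes were chosen for log2 ratios of at least 1 in size, so a reversal was unlikely from the start. No list that stood apart before the trend was removed reversed direction either. The complement and coagulation median, -0.21 and apart only after removal, was 0.14 with a 5 CPM filter. The alternatives with the trend removed were chosen after the data were seen. The counts of higher and lower genes, 1029 and 678, and of RBP genes, 30 and 3, stayed within 1.5 times with median-of-ratios or upper quartile factors, a prior count of 2 or an assumed coefficient of variation of 0.2. Total counts gave 1657 higher genes and 54 higher RBP genes, by moving every ratio alike. No expression filter gave 1443 lower genes, and a filter at 5 CPM gave 225 lower genes and 1 lower RBP gene, since fewer or more genes enter. A 1.5-fold threshold gave 2813 and 2009 genes and 108 and 69 RBP genes, and a 4-fold threshold 55 and 111 genes and 1 and 1 RBP genes. Requiring the interval to lie wholly beyond 2-fold gave 340 and 239 genes and 14 higher RBP genes. An assumed coefficient of variation of 0.4 gave 125 and 166 genes and 2 higher RBP genes. Removing the trend with GC content gave 328 higher genes and 7 and 13 RBP genes, and removing that with GC content and length gave 363 higher genes and 6 and 10 RBP genes. List medians that left their interval with total counts were SR proteins 0.41, m6A and m5C machinery 0.66, ribosomal proteins -0.52, 3' end processing 0.48, epithelial genes 0.24, mitosis 1.12, glycolysis 0.24, oxidative phosphorylation -0.20, antigen presentation -0.21, unfolded protein stress 0.28, growth factors 0.22 and histones -0.38. With the trend with GC content removed they were ribosomal proteins -0.63, epithelial genes 0.14, mitosis 0.65, mitochondrially encoded genes -0.49, antigen presentation -0.27 and growth factors 0.26. With GC content and length removed they were ribosomal proteins -0.48, 3' end processing 0.059, epithelial genes 0.17, mitosis 0.63, glycolysis 0.23, oxidative phosphorylation -0.19, antigen presentation -0.21 and histones -0.35. Without a filter it was histones, -0.36. Of 42 lists, 16 changed the sign of their median under at least 1 alternative, none of which stood apart before the trend was removed. With the trend with GC content and length removed, 116 named genes left their counting interval and 43 did not, and with total counts 72 did and 88 did not. Chromosome medians were not run, and runs of neighbouring genes in RefSeq order were tested instead. The authors' normalised values were not run, because the table holds counts only. No paired analysis was possible because each line has 1 library. Depth limited genes of few reads, such as CELF5. Apart from total counts, which moved every ratio, and the filters, which changed the genes entering, the cause was not tested.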

Other observations

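Antigen presentation genes were lower as a group in the MHCC97H library, with a median log2 ratio of -0.38 over 18 genes, or -0.21 with the trend with GC content and length removed. No member met the size rule, and the abundant B2M had a log2 ratio of -0.31. Interferon-stimulated genes had a median of 0.02 over 35 genes, with SAMD9 (1.46) higher and MX1 (-1.30) and IFI6 (-1.08) lower, of which MX1 alone still met the size rule with the trend removed (SAMD9 0.65, IFI6 -0.59). Cytokines and chemokines had a median of -0.15 over 25 genes. Those higher were IL1B (2.00, interval 0.80 to 3.62), CXCL11 (1.06) and IL33 (1.06, interval 0.13 to 2.12). IL1B and IL33 stood at only 1.07 and 1.17 CPM in the MHCC97H library. CCL26 (-3.91, interval -7.36 to -2.26), IL23A (-1.33), the NF-kappaB inhibitor gene NFKBIA (-1.28) and MDK (-1.01) were lower. With the trend removed, CXCL11 (0.41), IL33 (0.32) and MDK (-0.43) no longer met the rule. None of the 43 cancer-testis antigen genes in the table passed the expression filter.

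Metabolic lists mostly did not stand apart. Of 26 glycolysis genes, the hexokinase gene HK2 (1.46) was higher, and the abundant GAPDH and PKM had log2 ratios of -0.38 and -0.47. The list median was 0.07, and with the trend removed it was 0.23, above random lists (percentile 99.9). Hypoxia-inducible genes had a median of -0.06 over 29 genes, with P4HA1 (1.01, or 0.49 with the trend removed) higher and STC2 (-1.80) lower, and SLC2A1 and DDIT4 at 0.22 and -0.15. Cholesterol synthesis genes had a median of -0.14 over 24 genes, with DHCR7 at -0.59. Genes of fatty acid synthesis and lipid droplets had a median of -0.07 over 30 genes, with GPAM (1.39) and ELOVL6 (1.11) higher and PLIN1 (-1.06) lower, none of which met the rule with the trend removed (0.77, 0.50 and -0.87). Autophagy and lysosome genes had a median of -0.18 over 30 genes, including SQSTM1 (-0.65) and ATP6V0D1 (-0.48), and stood below random lists only with the trend removed (-0.15, percentile 1.12).

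The trend removal and the tests on neighbouring genes and on osmolyte genes were chosen after the data had been seen, and the test of whether the trend accounts for the osmolyte genes was chosen after their values were seen. The dependence of the ratio on GC content may come from base composition bias in preparing or sequencing the libraries. If so, long noncoding RNA genes should show it too, and the difference in median log2 ratio between the lowest and the highest of 3 equal groups by GC content was 0.55 among 1386 such genes and 0.93 among 12135 protein-coding genes, a ratio of 0.590. Transcript length was not separable from this: within 10 equal groups by GC content, the difference between longer and shorter genes was 0.442 of its size without the split. Runs of 25 neighbouring genes differed together before removal, with a largest median of 0.88 against 0.80 for the highest of 1000 shuffles, but after removal it was 0.431 against 0.573, so the trend may account for them. With 1 library per line, a biological difference that follows GC content stays open.

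A further pattern is the set of lists that lean beyond this trend. If the trend were the whole cause, its removal would bring each list toward 0. The corrected medians were 0.633 for mitosis, 0.649 for DNA replication, -0.470 for NRF2 targets, -0.536 for hepatocyte genes and -0.477 for ribosomal protein genes. All lay outside the central 95% of random lists, so the trend as fitted here did not account for the whole of these medians. These lists were among those that stood apart before removal. The fit used 1 transcript per gene and the random lists were matched on expression only, so a remainder of the trend is not excluded. A candidate explanation is a difference in growth state or density between the cultures, which the design cannot separate from the difference between the lines. Corrected values for ribosomal protein genes may depend on which transcript supplies the length and GC content, which was not tested.

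Another pattern links SLC6A12, SLC5A3 (-1.17) and FXYD2, all lower in the MHCC97H library and known to respond to osmotic stress. The hypothesis was that the cultures differed in osmotic stress, and 8 other osmotic-response genes, not looked at before, were set as its test, with a median of -0.5 or less counting for it and one above -0.25 against it. The median of the 7 kept genes was 0.157, which by the preset criterion counted against the hypothesis. Those genes ran from -1.95 (AKR1B1) to 1.64 (HSPA4L), a spread, weighed only after the result was seen, too wide to exclude the hypothesis. With the trend removed, a measure the criterion did not name, their median was -0.42 at percentile 0.55. That value lay between the limits of -0.5 and -0.25. With the trend removed, the median of SLC6A12, SLC5A3 and FXYD2 was -1.92, against -2.25 before, so the fitted trend did not account for it. SLC6A12 and FXYD2 were among the leading lower genes, which made this outcome likely from the start. SLC5A3 itself moved from -1.17 to -1.92, and it overlaps MRPS6, so its reads are not certain to be its own.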
